A study of Mus musculus with 4 samples.

How the data were processed

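Total RNA of HC11 cells was analysed on a 2-colour miRNA array run by a service provider, LC Sciences. Per the labels' protocols, small RNAs were separated by size, extended with a poly(A) tail and joined to a tag that was later stained with Cy3 or Cy5. Per the file headers, the deposited scanner tables give the mean intensity of each spot and its standard deviation in 1 dye channel per sample. These values still held the background and were not normalized. Each table had 3968 spots, of which 3500 belonged to 700 miRNA probes and 468 to controls, 180 of them empty. The authors also deposited a value table of processed intensity per probe and sample, with medians of 13.9, 15.1, 14.0 and 13.6 for proliferating replicate 1, differentiated replicate 1, differentiated replicate 2 and proliferating replicate 2. Each of its columns correlated best with its own sample's values across the 172 tested probes (r of 0.984 to 0.997). For this the scanner values were background-corrected and normalized as described below. How the authors' table was scaled and centred stays unknown. The image software is not given in the sources used here.

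The samples were grouped by the stage in the labels, with 2 per group. Same-numbered samples carried opposite dyes and opposite stages, and the series' design text describes 2-colour arrays with dye swaps, so each replicate number was taken as 1 shared array. Deviations of same-numbered samples from their group means had a correlation of 0.338 across probes, the same for both numbers by construction. The labels conflict on the unit of epidermal growth factor, and its concentration is not used here. The groups, tests, lists, named-miRNA rule and most alternatives were fixed before the data were examined.

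Empty spots averaged 152.5, 39.1, 287.8 and 86.2 intensity units in the sample order given above, and the median spread between the 5 spots of a detected probe was 17.1%, 18.4%, 10.1% and 13.1% of its mean. The scanner tables gave no local background, so the 20th percentile of all spots within 7 rows and columns was used. A probe was detected where its signal over that background was above the mean of the empty spots by more than 3 of their SDs in at least 3 spots. Background was corrected with normexp and an offset of 50 in limma 3.58.1 under R 4.3.3. Ratios were normalized by loess within each array (span 0.3, control spots given weight 0), and the 5 spots of a probe were averaged. The 172 probes detected in both samples of at least 1 stage were tested with lmFit and eBayes on the log2 ratio of differentiated over proliferating cells, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom and a prior of 2.08. An exact permutation test of 2 against 2 samples cannot go below 0.333.

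A probe undetected in both samples of a stage was given a bound: the bright stage's mean against the dim stage's mean of, per sample, the higher of the lowest signal among detected probes and the probe's own, in log2 values after loess and Aquantile. Fold changes of dim probes are understated by the offset. On simulated data for this comparison with 151 tested probes, 15 of 15 probes raised by a log2 ratio of 2 and 12 of 14 lowered by as much were called, as were 5 of 12 raised by 1 and 7 of 12 lowered by 1, and 0 of 92 unchanged ones. The median estimates fell short of the simulated log2 ratios, at 1.73 for 2, -1.59 for -2, 0.58 for 1 and -0.765 for -1. The simulated noise between spots and between samples was chosen, not fitted to these arrays. Simulated changes went both ways in similar numbers, with no shift of the miRNA probes as a whole. The simulation therefore gives no rate of false calls for the real data.

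Lists of miRNA families, clusters and markers, 24 in all, were matched by probe name, and the 13 with at least 3 tested members were tested with camera at a preset correlation of 0.01. Named miRNAs were the 12 with the largest rise and the 12 with the largest fall among called probes of the same sign on both arrays; members of lists were named as examples by mean signal from the highest, and some further members were named after their values were seen. The alternatives covered background, normalization, filters, the array block, dye as a covariate, the authors' table, eBayes options, thresholds and left-out samples. Centring on spike controls and 2 further backgrounds were added after seeing the data. miRNA genes within 10 kb of each other were taken from a RefSeq gene table of GRCm38.p6, used for names and neighbours only, in which 122 tested probes matched 1 gene. The genome build behind the array's design is not given in the sources used here.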

Results

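MicroRNA levels were measured in HC11 cells, a mouse mammary epithelial line with stem-like properties, at 2 stages. Proliferating cells were kept in 10% serum with epidermal growth factor and collected after 48 h. Differentiated cells were first held for 48 h in 2% serum without that factor, then given 100 nM dexamethasone and 1 µg/mL ovine prolactin, the lactogenic hormones, for 72 h. Each stage had 2 samples, and each of the 2 arrays carried a proliferating and a differentiated sample in opposite dyes, with the dyes swapped on the other array. The array held 700 mouse miRNA probes in 5 spots each. The comparison asked which miRNAs differed between the stem-like and the differentiated stage. The labels do not say whether the samples of a stage were separate cultures, so p-values measure only the spread between these samples, which may be technical. Because the dyes were swapped between the arrays, that spread, and each SD over the 2 arrays, also holds the probe's dye effect. With 2 arrays the dye effect cannot be separated from a difference between replicates. The number of arrays, 2, limits the precision of every value.

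The differentiated cells had 155 miRNA probes detected in both samples and the proliferating cells had 135. Both samples of both stages detected 118 probes, among them the let-7 family, miR-23a, miR-23b, miR-21 and miR-205. A further 37 probes were detected in both differentiated samples but not in both proliferating ones, and 17 were in the opposite position. Neither proliferating sample detected miR-146a, miR-146b, miR-152, miR-200c or miR-143, and neither differentiated sample detected miR-106a, miR-18a, miR-20b or miR-1983. Single samples detected 203 probes in proliferating replicate 1, 187 in differentiated replicate 1, 165 in differentiated replicate 2 and 138 in proliferating replicate 2. The detection counts differed more between the arrays than between the stages.

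miR-200a, miR-148a, miR-21 and miR-26b were higher in the differentiated cells, and miR-17, miR-20a, miR-92a and miR-222 were lower, each in the same direction on both arrays. In total 29 of the 172 tested probes rose and 23 fell at a limma adjusted p under 0.05. When the ratios were centred on the spike control probes instead of the miRNA probes, a setting chosen after seeing the data, 117 rose and 8 fell, and the share of calls that rose went from 55.8% to 93.6%. Directions below are therefore relative to the bulk of miRNA probes, whose median log2 ratio moved from 0.11 to 1.35 with that centring.

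**Figure D1:**
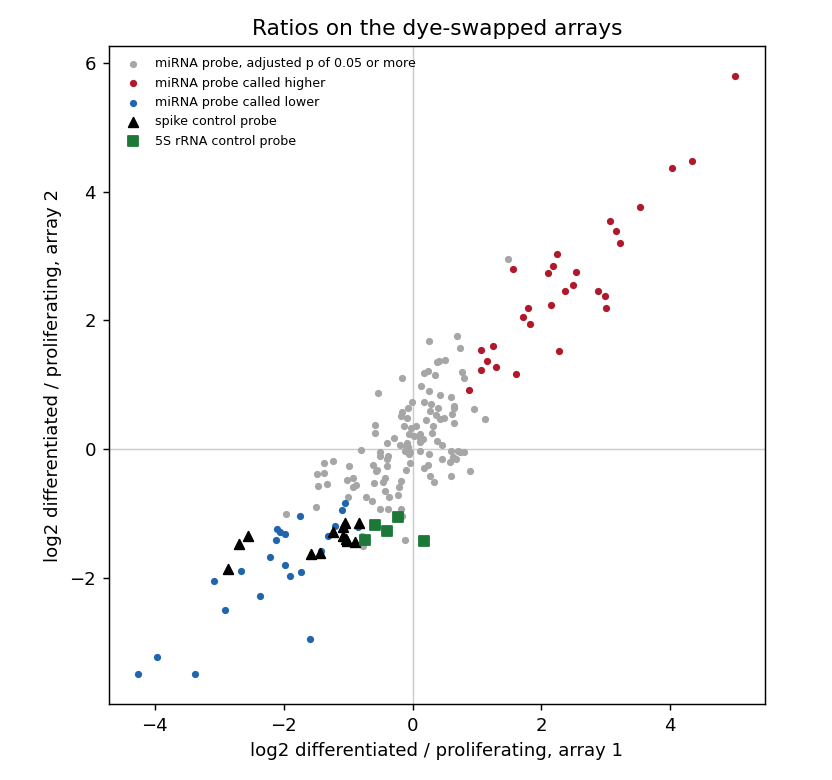
Log2 ratio of differentiated over proliferating cells on array 1 (horizontal axis) and array 2 (vertical axis), 1 point per tested miRNA probe and per detected control probe, coloured by the limma call. The miRNA ratios had a Pearson r of 0.922, and all 13 detected spike probes lay below 0 on both arrays.

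Across the 172 tested probes the ratios of the 2 dye-swapped arrays had a Pearson r of 0.922 and a Spearman rho of 0.858. This is a description across probes, which are not independent replicates. The sign was shared by 138 probes (80.2%) and by all 52 called ones, from miR-2138 at the top to miR-17 at the bottom. With 2 arrays a probe of opposite signs could hardly be called, so the shared sign of the called ones is no separate evidence of agreement.

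Among the probes with the largest rise, miR-2138 had a log2 ratio of 5.40 ± 0.56 (SD, n = 2 arrays; adjusted p = 0.00873), although only 1 of the 2 proliferating samples detected it. miR-146b was at least 17.2-fold higher in the differentiated cells (adjusted p = 0.00873), with no detection in either proliferating sample. miR-2134 had a ratio of 4.19 ± 0.24 and miR-2132 of 3.21 ± 0.01, each detected in 1 of the 2 proliferating samples. For miR-2138, miR-2134 and miR-2132 the proliferating signal over background on array 2 was 41.98, 18.66 and 32.52. This was under that sample's detection margin of 53.68. Their ratios on array 2 are therefore understated by the offset, and the SD does not measure how well the arrays match. miR-2143 was at least 5.46-fold higher (adjusted p = 0.0103). miR-1224 rose by 3.31 ± 0.34 and miR-762 by 2.64 ± 0.56. miR-148a, an abundant miRNA of milk, rose 9.67-fold (log2 ratio 3.27 ± 0.16; adjusted p = 0.00873). miR-21 was 6.03-fold higher (2.59 ± 0.57; adjusted p = 0.0164).

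**Figure D2:**
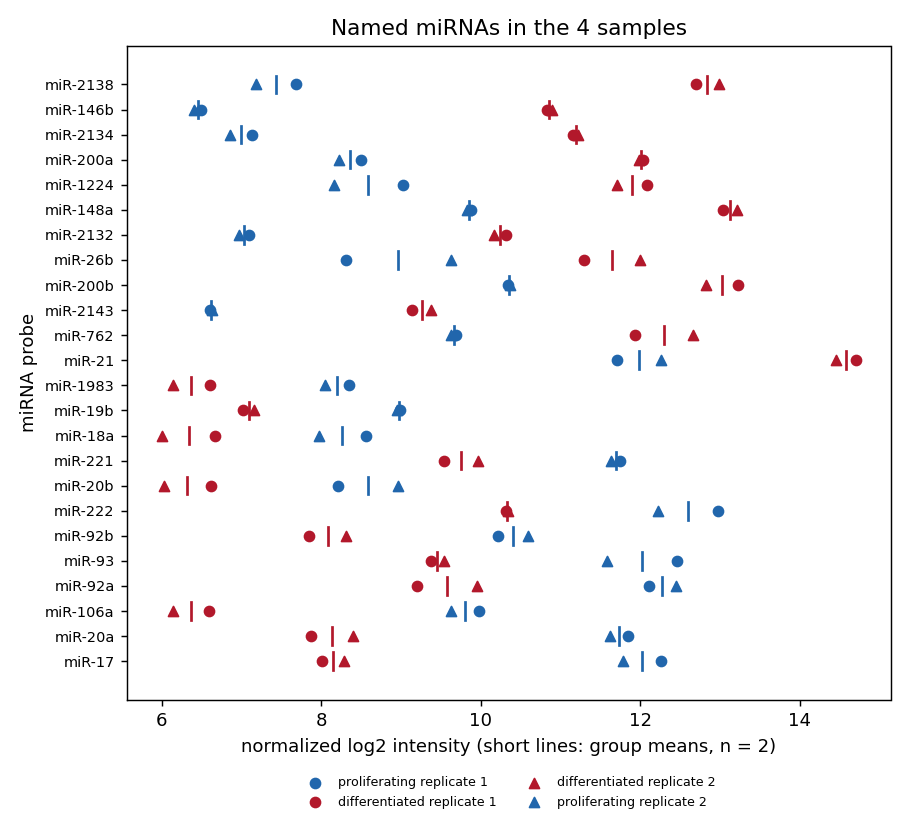
Normalized log2 intensity (horizontal axis) of the 12 miRNAs with the largest rise and the 12 with the largest fall among called probes, 1 symbol per sample and a short line at each group mean (n = 2). Both differentiated samples lie on the same side of both proliferating samples for each of these probes, with miR-17 at a mean of 8.15 in differentiated and 12.02 in proliferating cells.

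miR-17, miR-20a, miR-92a and the other tested members of the miR-17-92 and paralog clusters, which are known to promote proliferation, fell together. All 10 tested members fell, adjusted over all probes and adjusted over the list alone, with a median log2 ratio of -2.42 and a camera adjusted p of 6.13e-06 (adjusted p = 0.901 with an estimated correlation, which rests on 1 residual degree of freedom). miR-17 was 14.7-fold lower in the differentiated cells (log2 ratio -3.87 ± 0.54; adjusted p = 0.0103) and miR-20a 12.1-fold lower (-3.59 ± 0.53). miR-106a was at least 8.52-fold lower, with no detection in either differentiated sample. miR-92a was at -2.70 ± 0.29, miR-93 at -2.57 ± 0.74 and miR-25, the brightest member, at -1.65 ± 0.47. The targets of miR-106a, miR-20a, miR-20b and miR-93 differ from that of miR-17 by 1, 2, 2 and 3 edits, so these probes can share signal. miR-92b, of the same seed as miR-92a, was at -2.32 ± 0.06. Centred on the spikes, the median of the clusters was -1.18 and 6 members fell.

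miR-221 and miR-222, which restrain the cell-cycle inhibitor p27, both fell, miR-222 by 4.84-fold (-2.28 ± 0.55; adjusted p = 0.0201) and miR-221 by 3.85-fold (-1.95 ± 0.38; adjusted p = 0.0197). Only miR-222 was still called with spike centring. With 2 tested members this list had no set test. miR-1983 was at least 2.79-fold lower (adjusted p = 0.0151).

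miR-200a, miR-200b and miR-429 of the miR-200 family, miRNAs that maintain the epithelial state, were higher in the differentiated cells. miR-200a rose 12.5-fold (3.65 ± 0.16; adjusted p = 0.00873), miR-200b 6.37-fold (2.67 ± 0.30; adjusted p = 0.0103) and miR-429 had a log2 ratio of 1.43 ± 0.26. The remaining tested member, miR-200c, undetected in the proliferating cells, was at least 1.31-fold higher and was not called (adjusted p = 0.146). The same 3 members passed when adjusted over the list alone. The family's median was 2.05 with a camera adjusted p of 0.0477 (adjusted p = 0.901 with an estimated correlation).

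The miR-30 family had 3 of its 5 tested members higher, miR-30b at 2.41 ± 0.06, miR-30d at 1.30 ± 0.34 and miR-30c at 1.14 ± 0.12, and 4 when adjusted over the list alone. Its camera adjusted p was 0.0477 (adjusted p = 0.901 with an estimated correlation), and the call was lost in the fit without the replicate block at 0.141. Both tested members of the miR-26 family rose, miR-26b by 2.68 ± 0.43 and miR-26a by 1.89 ± 0.53. Of the lactation-linked list, miR-148a and miR-152 were the tested members, and both rose. Of the 6 tested members of the growth and hypoxia-responsive list, miR-21, miR-146b and miR-146a rose and miR-132, miR-155 and miR-210 were not called; the list had a median of 1.39 and a camera adjusted p of 0.134, and it was called with the authors' value table at 0.0472.

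**Figure D3:**
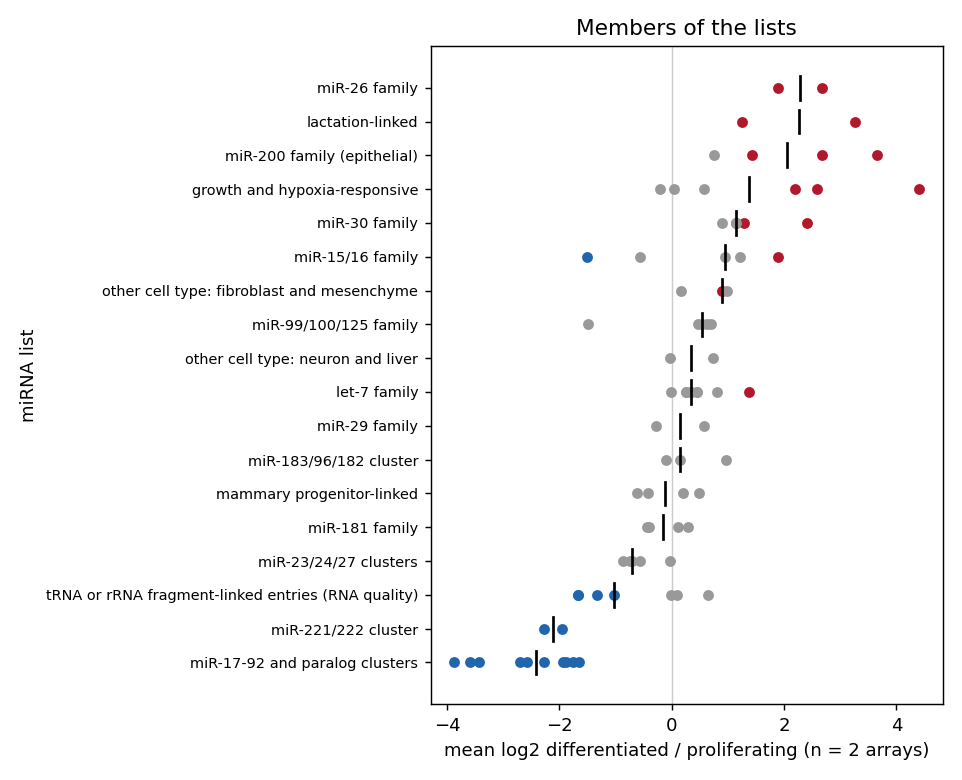
Mean log2 ratio over 2 arrays (horizontal axis) of each tested member of the lists with at least 2 tested members, red where called higher, blue where called lower and grey where not called, with a black line at the list median. The miR-17-92 and paralog clusters lie lowest at a median of -2.42 and the miR-26 family highest at 2.29; with spike centring these medians were -1.18 and 3.52.

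Of the 9 let-7 family members 1, let-7g, rose (1.39 ± 0.30; adjusted p = 0.03), and none passed when adjusted over the list alone; let-7c, let-7b and let-7a had values of 0.26 ± 0.59, 0.34 ± 0.52 and 0.34 ± 0.55. None of the 5 tested members of the miR-23/24/27 clusters was called, with a median of -0.71 that turned to 0.53 with spike centring. The miR-15/16 family went both ways, miR-15b being 2.83-fold lower (adjusted p = 0.0197) and miR-195 higher (1.89 ± 0.08; adjusted p = 0.0141), with a camera adjusted p of 0.759. No member was called in the family of miR-99, miR-100, miR-125a and miR-125b (5 tested, median 0.53), the miR-181 family (4 tested, median -0.15, or 1.09 with spike centring), the cluster of miR-183, miR-96 and miR-182 (3 tested, median 0.15), the miR-29 family (2 tested, median 0.15), the family of miR-34 and miR-449 (miR-34a alone tested, 0.17 ± 0.48) or the mammary progenitor-linked list (4 tested, median -0.11, or 1.13 with spike centring). Those of these lists that were tested with camera, the let-7 family and the miR-23/24/27 clusters included, had adjusted p-values from 0.193 to 0.759. Some medians moved between arrays. Without array 1 and without array 2 they were 0.10 and -0.31 in the miR-181 family and 0.12 and -0.39 in the progenitor-linked list. In the miR-183 cluster they were 0.37 and 0.26. With spike centring, higher calls numbered 9 of 9 in the let-7 family, 4 of 5 in that of miR-99, miR-100 and miR-125, 3 of 4 in the miR-181 family, 3 of 3 in the miR-183 cluster, 2 of 2 in the miR-29 family, 1 of 1 in that of miR-34, 3 of 4 in the progenitor-linked list, 3 of 5 in the miR-15/16 family and 1 of 5 in the miR-23/24/27 clusters, and none of these members was called lower. Spike centring took the spikes' mean of -1.237 out of every mean ratio, with no error for the spikes. The named miRNAs all had a standard error of 0.382 in that fit. A probe at 0 before centring would thus be called higher, and these higher calls follow largely from the shift. They are not separate results on these members. miR-205 of the progenitor-linked list, known from mammary progenitors, had a value of 0.20 ± 0.52.

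Of 7 tested entries linked to tRNA or rRNA fragments, read as signs of RNA quality, 4 fell, miR-1937b at -1.67 ± 0.61, miR-1937a at -1.67 ± 0.54, miR-805 at -1.33 ± 0.03 and miR-720 at -1.02 ± 0.10. The same number fell when adjusted over the list alone, and miR-2145 (0.65 ± 0.004) then passed as higher. As a list they were not called, with a camera adjusted p of 0.193. The median of -1.02 turned to 0.21 with spike centring, which called 3 entries higher and 0 lower.

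Markers of other cell types were mostly undetected. None of the 19 Dlk1-Dio3 cluster probes and neither endothelial probe was detected in any sample, and the blood list had miR-486 alone in some samples. Among the fibroblast and mesenchyme list, miR-143 was at least 1.51-fold higher in the differentiated cells (adjusted p = 0.0474), while miR-145, at least 1.57-fold higher (adjusted p = 0.0564), and miR-140 (0.17 ± 1.00) were not called; 2 members rose when adjusted over the list alone, and the camera adjusted p was 0.318. miR-206 of the muscle list was lower (-1.03 ± 0.26; adjusted p = 0.0483), with a value of 0.21 when centred on the spikes. In the neuron and liver list miR-128 and miR-9 were tested and not called, and of the pluripotent stem cell clusters only miR-290-5p was tested (0.20 ± 0.41).

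None of the 13 lists was called with an estimated correlation (0 at an unadjusted p under 0.05) or with fry (4 at that level), while 3 were called with the preset correlation. Fits on the authors' value table called 48 higher and 56 lower.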

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

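The dye and 5S rRNA tests below, and the use of bootstrap intervals beside the loess bound, were chosen after the result was seen. Spike control probes, which lie outside the miRNA comparison, read lower in the differentiated samples, with a log2 ratio of -1.24 averaged over the arrays (-1.07 and -1.40), as did the 5S rRNA probes at -0.84 (-0.40 and -1.27). A dye effect would turn its sign between the arrays, and 13 of 13 detected spike probes were below 0 on both. Loess bending as the cause is argued against on array 2, where the spike median was -1.375 with median centring and no loess (bootstrap 95% interval -1.41 to -1.29). On array 1 it was -0.688 (-1.25 to -0.39), against -1.07 with loess, so it was below 0 without loess as well; the preset bound of -0.5 lies inside the interval, and the test did not decide for this array. More small RNA of every kind in the differentiated channels may also lower the spikes; the 5S probes lay 0.675 above them on array 1 and 0.125 on array 2, which does not decide it, and the spike amounts are not given in the sources used here.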

How the results depend on the processing

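Spike centring, the background from empty spots and the fit with no local background were chosen after seeing the data. The main counts were 29 higher and 23 lower. They became 46 and 43 with offset 16, 48 and 46 with loess on detected probes, 50 and 58 with quantile normalization, 48 and 56 with the authors' table, 41 and 47 with plain subtraction, 39 and 35 with median centring, 18 and 17 on probes detected in all 4 samples, 21 and 13 with no filter, 24 and 13 above the median signal, 6 and 1 at 0.01, and 117 and 8 with spike centring. The cause was not tested, except that other filters change how many probes are tested. Spike centring turned the sign of 4 of the 52 called probes (miR-130a, miR-206, miR-674 and miR-720, none then called). Without the replicate block 38 rose and 33 fell, and 26 and 22 with dye as a covariate. Leaving out each sample of the fit with no block, where the lone sample is assumed to vary like the other stage, gave 21 to 35 higher and 19 to 31 lower, the lowest of each without differentiated replicate 2. Each array alone gives values with no test.

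All 24 named miRNAs kept their direction in each alternative that tested them. They were picked as the largest calls with the same sign on both arrays, so this is a weak test. Direction was fixed by size with spike centring, and by reused mean ratios with other filters, no block, dye as a covariate and eBayes options. Setting aside the fits that left out a sample, 7 of the 24 missed the threshold with no filter and 4 above the median signal. With spike centring 4 missed it, and 1 each with eBayes trend and eBayes robust. Among probes detected in all 4 samples only 15 of the 24 were tested, and these passed. Without differentiated replicate 2, miR-26b had a log2 ratio of 2.32, against 2.68 in the main fit. The miR-17-92 clusters and the miR-200 family each lost their call with an estimated correlation (0.901) and fry (0.114). The miR-30 family lost it with those (0.901 and 0.206), without the replicate block (0.141), with loess on detected probes (0.0914), median centring (0.0792) and the authors' table (0.273). Calls were gained by the growth and hypoxia-responsive list with the authors' table (0.0472) and no filter (0.00353), and with no filter by the let-7 family (0.00477, higher) and the miR-23/24/27 clusters (0.0128, lower). Lists called higher numbered 2, or 1 with median centring, loess on detected probes or no replicate block, 4 with no filter, and 0 with the estimated correlation or fry. With 1 member per seed the count was also 0, because neither list kept enough members to be tested. Lists called lower numbered 1, or 2 with no filter and 0 with the estimated correlation or fry. The r between arrays was 0.891 with median centring and 0.893 with plain subtraction or no filter. Detection counts stayed within 1.5 times in every alternative run. Dim probes such as miR-146b and miR-106a are limited to bounds.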

Other observations

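The tests of cross-hybridisation and of structural RNA fragments below, and the interval beside the scaling test, were chosen after the result was seen. Outside the fixed lists, miR-10a (1.29 ± 0.01) and miR-1894-3p (at least 4.59-fold higher) rose, and miR-130a (-1.19 ± 0.01), miR-351 (-1.39 ± 0.50) and miR-674 (-0.94 ± 0.15) fell; centred on the spikes, miR-130a and miR-674 were at 0.04 and 0.29. miR-99b had a log2 ratio of -1.48 ± 0.68 and was not called (adjusted p = 0.0564), beside 0.45 for let-7e and 0.71 for miR-125a-5p, whose genes lie next to it. These miRNAs were named after their values were seen.

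Of 12 tested probes named miR-2132 to miR-2146, a group picked after its values were seen, 8 were called higher, 4 were not called and none was called lower, with log2 ratios from -1.07 (miR-2142, not called) to 5.40. Their median GC content was 61.6% against 47.8% in the other tested probes. Over these 160 others the ratio fell with GC content (slope -0.137 per 10 percentage points, Spearman rho -0.251). The 27 of them at or above 61.6% had a median of -0.011, with 3 called higher and 5 lower. These values argue against a general rise of GC-rich probes. Under that slope the linear correction could not lower GC-rich probes, and it took the members' median from 2.251 to 2.468 (bootstrap 95% interval 0.94 to 3.19). The interval rests on members picked after their values were seen. A rise of structural RNA fragments of every kind is argued against by the fixed fragment list, whose median was -1.023 with 4 entries lower; with spike centring it was 0.21, with 3 entries higher and 0 lower, against 3.49 for the pattern's members. Leaving out miR-2145, which is in both sets, the medians differed by 3.68 (bootstrap 95% interval 1.85 to 4.54), a difference that centring does not move, chosen after the result was seen; a smaller rise shared with the fragments stays open under spike centring. Of the 7 tested entries of the fragment list 3 were not called, so a rise of only some kinds of fragment stays open as well. A change with the stage stays open as a hypothesis, and what these probes capture was not tested.

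Members of the miR-17-92 and paralog clusters fell together. Cross-hybridisation of 1 family could lower several probes at once. All 10 tested members were called lower, so the 5 more than 4 edits from miR-17 were bound to be among them. Of these, miR-106b, at 5 edits, has the seed of miR-17, and miR-92a and miR-25 share a seed. Signal shared with miR-17 is argued against for miR-19b, miR-92a and miR-25, at 15, 13 and 13 edits (log2 ratios -1.88, -2.70 and -1.65). The choice of scaling is argued against as the whole cause at the median of the spikes, since the clusters' median stayed at -1.18 with that centring. Its bootstrap 95% interval (-2.19 to -0.61) resamples cluster members, some of which can share signal, and leaves out the spread of the spikes. Single spike probes ranged from -2.37 to -0.99, and the clusters' median before centring was -2.42. Centring on the lowest spike would thus leave little of the fall. The fall itself was measured on a list fixed before the data were examined, and why these clusters were lower in the differentiated stage was not tested.

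miRNAs from neighbouring genes were tested for closer ratios, as a hypothesis of shared transcription. Over 31 pairs within 10 kb with different seeds the median absolute difference was 0.82, against a median of 1.06 over shuffled pairs (one-sided permutation p = 0.17). No pair held miR-17, miR-18a, miR-19b, miR-20a, miR-92a, miR-221 or miR-222, so the test did not cover these. Some pairs held star strands, and probes recurred across pairs. The test did not pass, which does not show that neighbours differ as much as random pairs, and 8 pairs had opposite signs.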
